A study of Rattus norvegicus with 17 samples.

How the data were processed

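Gene expression was measured with Affymetrix arrays in 17 samples from 8-month-old rats that carry a mutation of Cdkn1b, the gene of the cell cycle inhibitor p27, on a mixed Sprague-Dawley and Wistar-Kyoto background, per the labels. Total RNA was extracted with a column kit that included DNase, amplified from small amounts by a whole-transcriptome kit and labelled with biotin, per the labels' protocols. The submitters' processing notes name RMA, with no version, and Affymetrix Expression Console 1.3.0.187. RMA corrects the background, normalizes the arrays to a common distribution of probe intensities and summarises the probes of a probe set. The deposited values were on a log2 scale, ranged from 2.22 to 13.7, and were used as deposited.

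The value table held 29214 probe sets for 17 arrays. The probe annotation paired 15310 probe sets with 1 gene symbol and 323 with several symbols, and did not list 13581. Of the 15310, 15279 were matched by gene identifier to a rat reference table, which changed 0 symbols. Where a symbol had several probe sets, the one with the highest mean over all arrays was used, which left 14506 genes, 527 of them with more than 1 probe set. Probe sets with several symbols or no listed symbol were not named. Genomic coordinates were not used here. No pair of arrays held identical values, and the highest correlation between arrays was 0.993. Precision is limited by the number of arrays, and probe sets below the lower quartile of an array, which lay between 3.65 and 3.91 on the log2 scale, have compressed differences.

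Samples were grouped by their labels into control (20 mg/kg polyethylene glycol, PEG, 7 samples), NVP-BEZ235 at 20 mg/kg (6 samples) and NVP-BEZ235 at 30 mg/kg (4 samples). The labels do not say that each sample came from a separate animal, so the p-values measure the spread between these samples. Linear models were fitted to each gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the 14506 genes, with a threshold of 0.05. The comparison of both doses together against control used treatment and sex as terms. The comparisons of each dose with control and of the doses with each other came from a fit of 3 groups with sex as a term, in which the groups shared an estimate of the spread. Male and female rats were compared in the treatment fit, and a product term tested the interaction of treatment and sex. The choices in this paragraph and the next were made before the data were examined.

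In all, 34 gene lists were fixed in advance, of which 33 were tested and 1 held sex-linked genes. Of 504 listed genes, 444 had a value; Mki67, Irs2 and the sex-linked genes were not analysed here. The lists covered cell types (gonadotroph, Pou1f1-lineage, corticotroph and melanotroph, folliculostellate and stem cell, posterior pituitary and glial, chromaffin, endothelial, fibroblast, pericyte and matrix, macrophage, lymphocyte, neutrophil and erythroid markers), the cell cycle (G2/M and mitosis, G1/S and DNA replication, D cyclins and cell cycle inhibitors), signalling (PI3K, AKT and mTOR pathway components, FOXO targets, immediate early genes, MAPK feedback genes, pituitary receptors, interferon response), metabolism and growth (sterol biosynthesis, fatty acid synthesis, ATF4 targets and amino acid supply, ribosome biogenesis, lysosome and autophagy, glycolysis and hypoxia, oxidative phosphorylation), stress and survival (apoptosis regulators, p53 targets, unfolded protein response, NRF2 and AhR targets) and the neuroendocrine secretory machinery. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 33 lists, with camera at an estimated correlation and fry beside it. For the G2/M and mitosis list, the mean log2 value per sample was also compared by an exact permutation test. The genes named for the main comparison were the 10 with the largest change in each direction past the threshold, a fixed set of hormone, cyclin and receptor genes, and up to 4 members of each list with the smallest p. For the other comparisons they were the 5 with the largest change in each direction past the threshold. Where none passed in a direction, the 3 with the smallest p were taken in these. Genes without an established symbol were passed over.

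After the data were examined, 4 further lists were added (adrenal cortex markers, class II antigen presentation, immunoproteasome and class I antigen presentation, and neuropeptides), and 5 further settings were run: the set of sample-title numbers as a term, each set alone (numbers 1 to 4, and 5 to 10), the SD of each array as a covariate, and a fit without replicates 3 and 4 at 30 mg/kg. The alternatives chosen in advance were a fit without sex, trended or robust variances, array weights, quantile normalization, median centring, all probe sets, the mean of a gene's probe sets, filters on dim probe sets at the 25th percentile or the median, stricter thresholds, female rats alone, the title number as a block, other codings of dose, fits of only the groups compared, and leaving out each sample in turn.

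The model step was tested on simulated data for the 14506 genes with the real group sizes. For treatment against control it recovered 44.3% of genes simulated with a log2 change of 0.5, 92.8% at 1 and 99.2% at 2, and 4.95% of calls were false. Recovery at a log2 change of 0.5 was 26.7% for 30 mg/kg against control, 37.5% for 20 mg/kg against control and 23.6% between the doses. The list test recovered a simulated shift of -0.3 of the sterol biosynthesis list in 50 of 50 draws, and 1 of the 50 draws had a falsely called list. The simulated noise was independent between genes. These rates therefore do not cover lists whose genes move together, for which the estimated correlation is given. The noise was also independent between arrays, with no difference between the sets of title numbers. The share of false calls therefore does not cover calls that such a difference gives in the real data. Plots were drawn with matplotlib 3.10.9.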

Results

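Transcript levels were measured on 17 arrays of tissue labelled pituitary adenoma from rats with a mutation of Cdkn1b. Of these, 10 came from rats given NVP-BEZ235, an inhibitor of phosphoinositide 3-kinase (PI3K) and mTOR, and 7 from control rats given PEG. The treated samples comprised 6 at 20 mg/kg (4 female, 2 male) and 4 at 30 mg/kg (3 female, 1 male), and the controls were 5 female and 2 male samples. The labels do not give the length of treatment, their protocol field names no treatment, and sample labels and the series design differ on whether the mutation was homozygous or heterozygous. Array medians lay between 4.95 and 5.11 on the log2 scale and upper quartiles between 6.85 and 7.10. The numbers in the sample titles run from 1 to 7 for controls, 1 to 4 for 30 mg/kg and 5 to 10 for 20 mg/kg. Arrays numbered 5 to 7 among the controls correlated with the 20 mg/kg arrays at a median r of 0.983 across genes, against 0.966 with control arrays 1 to 4. Control arrays 1 to 4 correlated at 0.966 with the 20 mg/kg arrays and at 0.955 with the 30 mg/kg arrays of their own numbers. The 30 mg/kg arrays correlated at a median of 0.947 with control arrays 5 to 7. By these medians they too lay closer to the controls of their own numbers, although they correlated less with either control set than the 20 mg/kg arrays did. Results are also given within numbers 1 to 4 (4 control, 4 at 30 mg/kg) and within numbers 5 to 10 (3 control, 6 at 20 mg/kg). In limma and camera the sex term takes up the only male of numbers 1 to 4, replicate 4 at 30 mg/kg, so those fits compare 4 control with 3 treated libraries, while permutations use all 4.

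The tissue markers of these libraries were those of the adrenal gland. The catecholamine enzymes Th and Dbh had mean log2 values of 12.29 ± 0.32 and 12.32 ± 0.25 (SD, n = 17), and the steroidogenic genes Cyp11a1 and Star had 12.02 ± 0.26 and 12.11 ± 0.19. The pituitary hormone genes had means below the upper quartile of the arrays, and all but Prl near or below the array median: Gh1 had 3.86 ± 0.42, Fshb 4.06 ± 0.19, Cga 4.12 ± 0.48, Tshb 4.21 ± 0.39, Pomc 4.64 ± 1.05, Lhb 4.99 ± 0.18 and Prl 5.61 ± 1.22. Prl reached 9.16 in control replicate 2 and Pomc 7.86 in replicate 3 at 30 mg/kg. The median of the 8 chromaffin markers lay between 8.04 and 10.69 in every array, and that of 11 adrenal cortex markers, listed after the chromaffin levels were seen, between 10.11 and 11.73. Levels of different probe sets are set here only against the quantiles of the arrays. The series title names pheochromocytoma, a tumour of adrenal chromaffin cells, while the sample labels name pituitary adenoma. The samples are called treated and control libraries below.

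**Figure D1:**
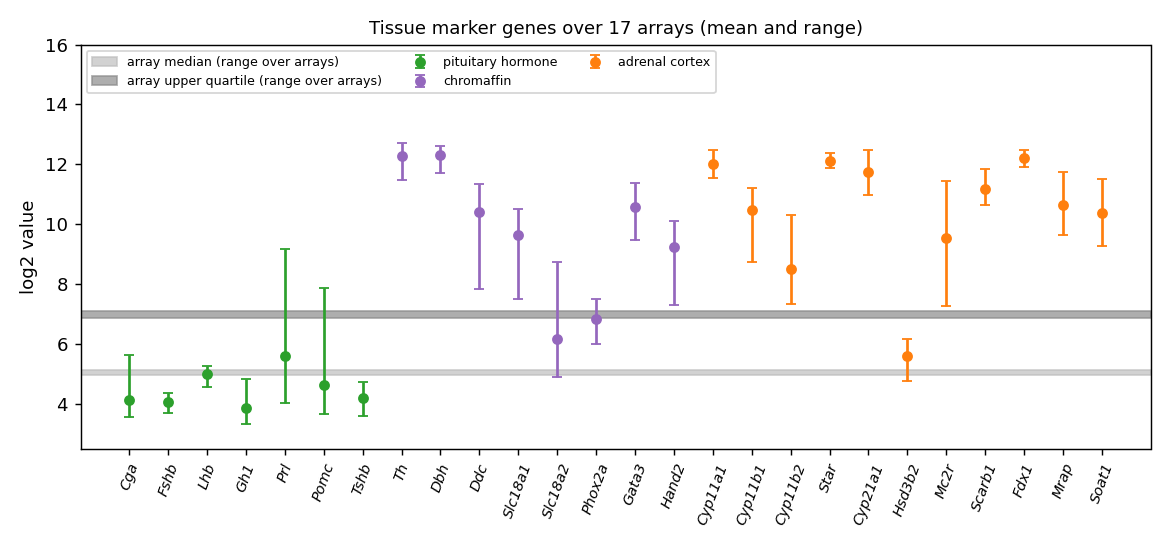
Log2 values (vertical axis) of 7 pituitary hormone, 8 chromaffin and 11 adrenal cortex genes; points are means over 17 arrays and bars the lowest and highest array, with grey bands for the range of array medians and upper quartiles. All 7 hormone genes have means below the upper quartile band, while Th, Dbh, Cyp11a1, Star and Fdx1 have means above 12.

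The comparison of all treated with all control libraries asks which transcripts differ after PI3K and mTOR inhibition. The largest decreases included interferon-induced genes, chemokines, globins and genes of lipid handling. Oasl, an interferon-induced gene (probe set 10762740), fell by 2.62 ± 0.22 on the log2 scale (SE; limma adjusted p = 6.6e-06), from 7.11 ± 0.78 (SD, n = 7) in controls to 4.48 ± 0.23 (n = 10). Ccl11, the chemokine eotaxin, fell by 3.16 ± 0.70 (adjusted p = 0.033) and Cxcl10, an interferon-induced chemokine, by 2.10 ± 0.37 (adjusted p = 0.010). Also among the 10 largest decreases were Fabp6, a bile acid binding protein (log2 change -2.92), Ifi27l2b (-2.02), Tnfsf10, the death ligand TRAIL (-1.84), and F11r, a junctional adhesion molecule (-1.78). The fatty acid desaturase Fads1 (-1.85) and the globins Hbb-b1 (-2.45) and Hbb (-2.40) completed them. Hbb and Hbb-b1 are near-identical copies whose probes can cross-hybridise, so they are not independent measurements.

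The largest increases were smaller. Creb3l1, a membrane-bound transcription factor, rose by 1.73 ± 0.36 on the log2 scale (SE; limma adjusted p = 0.025), from 7.41 ± 0.70 (SD, n = 7) to 9.14 ± 0.87 (n = 10). The synaptic vesicle gene Sv2c rose by 1.66 ± 0.30 (adjusted p = 0.014), the phosphodiesterase Pde10a by 1.59 ± 0.29 (adjusted p = 0.015), Gpnmb by 1.12 ± 0.18 (adjusted p = 0.0065) and Depp1, a known FOXO target, by 1.08 ± 0.17 (adjusted p = 0.0054). Atp13a3 (0.97), Rai14 (0.95), Ifrd1 (0.93), Luc7l (0.93) and Sdk2 (0.90) made up the 10 largest increases. For all 20 of these genes, all 10 treated libraries lay on the called side of the control mean. Cdkn1b itself did not pass (0.28 ± 0.17, adjusted p = 0.50), while Ccnd1, the gene of cyclin D1, fell by 0.77 ± 0.18 (adjusted p = 0.042), lower in 10 of 10 treated libraries. Of the 20 genes, only Oasl and Cxcl10 passed in female rats alone, and leaving out control replicate 7 ended the calls of Creb3l1, Atp13a3, Rai14, Ifrd1, Sdk2, Ccl11, Hbb-b1, Hbb and Ifi27l2b. The calls of Atp13a3, Rai14 and Ccnd1 were also lost without most other single libraries.

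In all, 215 of 14506 genes passed the threshold, 75 higher and 140 lower, and 59 of them by at least 2-fold. Within numbers 1 to 4, 16 genes passed and within numbers 5 to 10, 173, of which 12 and 78 were among the 215. Of the 20 named genes 5 and 9 passed there, Creb3l1, Pde10a, Ifi27l2b and Tnfsf10 in both. With the set as a term 712 passed, all 215 among them. The count was 100 without the sex term, 12 in female rats alone, 424 with array weights, and 138 among genes above the median. With median centring 83 rose and 101 fell. It was 110 without control replicate 1, 141 without control replicate 4, 71 without control replicate 6 and 46 without control replicate 7. It was 122 without replicate 1 at 30 mg/kg, and 139, 119 and 97 without replicates 7, 8 and 10 at 20 mg/kg.

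**Figure D2:**
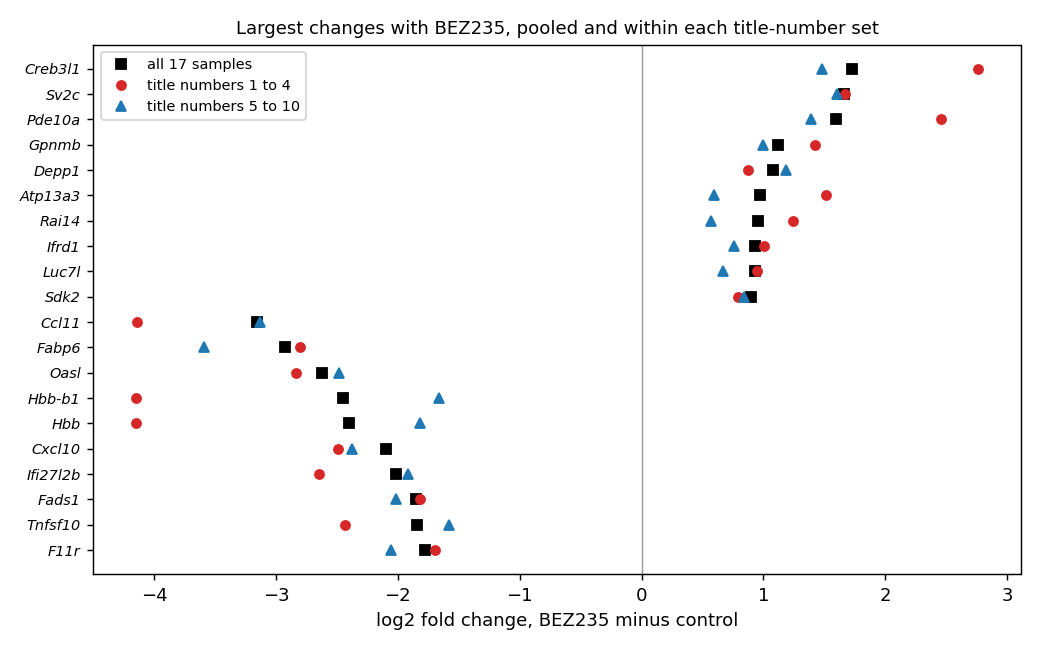
Log2 fold change, BEZ235 minus control (horizontal axis), of the 10 genes with the largest increase and the 10 with the largest decrease; squares are the fit to all 17 samples, circles title numbers 1 to 4 and triangles numbers 5 to 10. The genes were chosen by the fit to all samples, in which Ccl11 lies at -3.16 and Creb3l1 at 1.73.

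Of the 33 lists, 16 passed camera with the preset correlation, 9 lower and 7 higher, and 3 also passed with an estimated correlation. Of the 16, 13 passed camera with the preset correlation within numbers 1 to 4, all but the fibroblast, sterol and oxidative phosphorylation lists. Within numbers 5 to 10, 14 did, all but the unfolded protein response and ribosome biogenesis lists. Of those called within numbers 5 to 10, exact permutation of list means gave p = 0.36 for immediate early genes, 0.15 for lysosome and autophagy and 0.14 for macrophage markers. It gave 0.060 for fatty acid synthesis and for oxidative phosphorylation. Of those called within numbers 1 to 4, it gave 0.057 for macrophage markers and for fatty acid synthesis and 0.29 for the unfolded protein response. The other lists called there had p under 0.05. The interferon response list fell (mean log2 change -0.75, adjusted p = 8.8e-11; adjusted p = 0.023 with an estimated correlation). Of its 14 measured genes, 4 were lower over all genes tested and 10 adjusted over the list alone, with 0 higher. The antiviral GTPase Mx2 fell by 1.49 ± 0.23 (SE, adjusted p = 0.0042), and Oas1a and the transcription factor Irf7 by 0.75 and 0.77 (adjusted p = 0.027 and 0.050). The mean log2 value of the list was 6.05 ± 0.37 (SD, n = 7) in controls and 5.30 ± 0.18 (n = 10) in treated libraries. It was lower in treated libraries by 0.71 within numbers 1 to 4 and by 0.91 within numbers 5 to 10, with exact permutation p = 0.029 and 0.012, the smallest those group sizes can give. Markers of immune cells moved with it. The lymphocyte list fell (mean log2 change -0.43, adjusted p = 1.4e-06; adjusted p = 0.0035 with an estimated correlation), with 2 of 9 genes lower, Cd2 (-0.49) and Cd3d (-0.99), and 6 adjusted over the list alone; 8 of the 9 genes had means below the array median. The macrophage list fell by camera (mean -0.31, adjusted p = 0.017), a call lost at adjusted p = 0.41 with an estimated correlation. Of its 12 genes only Cd74, the class II invariant chain, passed over all genes (-1.49 ± 0.32, adjusted p = 0.030), and 3 passed adjusted over the list alone. The list call was lost without control replicate 6 (adjusted p = 0.079) or 7 (0.060) and without replicate 2 (0.053) or 4 (0.086) at 30 mg/kg.

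Genes of mitosis were also lower. The G2/M and mitosis list fell (mean -0.39, adjusted p = 3.0e-11; adjusted p = 0.076 with an estimated correlation), with 3 of 26 genes lower over all genes and 10 adjusted over the list alone. Topoisomerase Top2a fell by 1.38 ± 0.26 (SE, limma adjusted p = 0.015), Prc1 by 0.85 and Ccnb2 by 0.68 (both adjusted p = 0.042). The list mean per library was 4.15 ± 0.04 (SD, n = 10) in treated and 4.54 ± 0.35 (n = 7) in control libraries, and all 10 treated libraries lay below the lowest control (exact permutation p = 5.1e-05, two-sided, the smallest these groups can give). Controls spread most: the highest control mean was 5.20 and the lowest 4.27, near the array median or below it, and the difference was -0.20 in female rats alone (exact permutation p = 0.0013). It was -0.22 within numbers 1 to 4 and -0.65 within numbers 5 to 10 (exact permutation p = 0.029 and 0.012). Among the controls sex and title number go together, since both male controls are numbered 6 and 7, and the permutations within numbers 5 to 10 take no account of sex, so sex and title number are not separated there. The G1/S and DNA replication list did not pass (adjusted p = 0.052), although 1 of its 24 genes, Rrm2, fell by 1.31 ± 0.23 (adjusted p = 0.011), also the count adjusted over the list alone.

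Lipid synthesis genes were lower. The fatty acid synthesis list fell (mean -0.47, adjusted p = 0.00038; adjusted p = 0.12 with an estimated correlation), with 3 of 12 genes lower over all genes, the desaturases Fads1 (-1.85 ± 0.30) and Fads2 (-1.61 ± 0.25) and malic enzyme Me1 (-0.78 ± 0.17), and 4 adjusted over the list alone. The sterol biosynthesis list fell (mean -0.28, adjusted p = 0.00038; adjusted p = 0.18 with an estimated correlation). Of its 18 genes 0 passed over all genes and 5 adjusted over the list alone, led by squalene synthase Fdft1 (-0.66 ± 0.19, adjusted p = 0.10 over all genes). The sterol list mean differed by -0.51 within numbers 5 to 10 (exact permutation p = 0.024) and by -0.10 within numbers 1 to 4 (exact permutation p = 0.46).

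Erythroid markers fell (mean -1.10, adjusted p = 0.00055; adjusted p = 0.073 with an estimated correlation), with 2 of 4 genes lower, Hbb and Hba-a3 (-1.47 ± 0.32, adjusted p = 0.031), and 3 adjusted over the list alone. The fibroblast, pericyte and matrix list fell (mean -0.24, adjusted p = 0.0026; adjusted p = 0.097 with an estimated correlation). The collagen gene Col3a1 (-0.68 ± 0.11, adjusted p = 0.0064) was the gene of 12 that passed, and adjusted over the list alone 3 were lower and 1 higher. Oxidative phosphorylation genes were lower by camera (mean -0.11, adjusted p = 0.022), a call lost at adjusted p = 0.72 with an estimated correlation. None of the 23 passed over all genes or adjusted over the list alone (0 in both), and the mean was 0.03 in female rats alone. This call was lost without control replicates 5, 6 or 7 (adjusted p = 0.12, 0.12 and 0.32) and without replicates 1 or 4 at 30 mg/kg (0.11 and 0.29).

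Lists that rose included signalling feedback genes. The FOXO target list rose (mean 0.39, adjusted p = 0.00038; adjusted p = 0.023 with an estimated correlation). Of its 15 genes 0 passed over all genes and 6 adjusted over the list alone; Klf2 (0.71 ± 0.20) and Pdk4, an inhibitor of pyruvate dehydrogenase (1.43 ± 0.44), had adjusted p = 0.088 and 0.12 over all genes and were higher in 10 of 10 treated libraries. The insulin receptor gene Insr was 0.68 ± 0.23 higher (adjusted p = 0.15); in a fit of all probe sets its other probe set passed (0.65, adjusted p = 0.032) and the one used did not (adjusted p = 0.21). MAPK feedback genes rose (mean 0.51, adjusted p = 6.6e-05; adjusted p = 0.12 with an estimated correlation), with 2 of 11 genes higher, Spred1 (0.62 ± 0.12, adjusted p = 0.020) and Etv5 (0.90 ± 0.20, adjusted p = 0.034), and 5 adjusted over the list alone. Immediate early genes rose by camera (mean 0.52, adjusted p = 0.0011), a call lost at adjusted p = 0.44 with an estimated correlation, and 0 of 15 passed over all genes or adjusted over the list alone. At 20 mg/kg against all controls the mean change of this list was 0.13 (camera adjusted p = 0.57). Within numbers 5 to 10 the list means differed by 0.35 (camera adjusted p = 0.037, exact permutation p = 0.36). Replicate 10 at 20 mg/kg was highest in its group, with a list mean of 7.68 against 6.59 for the next library.

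Lysosome and autophagy genes rose (mean 0.16, adjusted p = 0.00096; adjusted p = 0.20 with an estimated correlation), with 2 of 23 genes higher, the autophagy genes Gabarapl1 (0.71 ± 0.11, limma adjusted p = 0.0054) and Sqstm1 (0.47 ± 0.11, adjusted p = 0.035), and 4 adjusted over the list alone. Unfolded protein response genes rose (mean 0.19, adjusted p = 0.00096; adjusted p = 0.29 with an estimated correlation), with 0 of 15 past the threshold over all genes and 4 adjusted over the list alone, led by Sel1l (0.44 ± 0.11, adjusted p = 0.061). The mean difference of this list was 0.25 within numbers 1 to 4 and 0.07 within numbers 5 to 10 (exact permutation p = 0.29 and 0.50; camera adjusted p = 0.025 and 0.12). Ribosome biogenesis genes rose (mean 0.12, adjusted p = 0.022; adjusted p = 0.29 with an estimated correlation), with 0 of 18 over all genes and 2 adjusted over the list alone; the call was lost without control replicates 2 or 4 (adjusted p = 0.073 and 0.067) and without replicates 6 or 7 at 20 mg/kg (0.054 and 0.053). The mean difference was 0.17 within numbers 1 to 4 and -0.03 within numbers 5 to 10 (exact permutation p = 0.029 and 0.71; camera adjusted p = 0.042 and 0.89), so no rise was seen in the second set. Endothelial markers rose (mean 0.26, adjusted p = 0.0044; adjusted p = 0.38 with an estimated correlation), and of 12 genes the VEGF receptor Flt1 passed (0.74 ± 0.17, adjusted p = 0.033), as it did adjusted over the list alone.

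**Figure D3:**
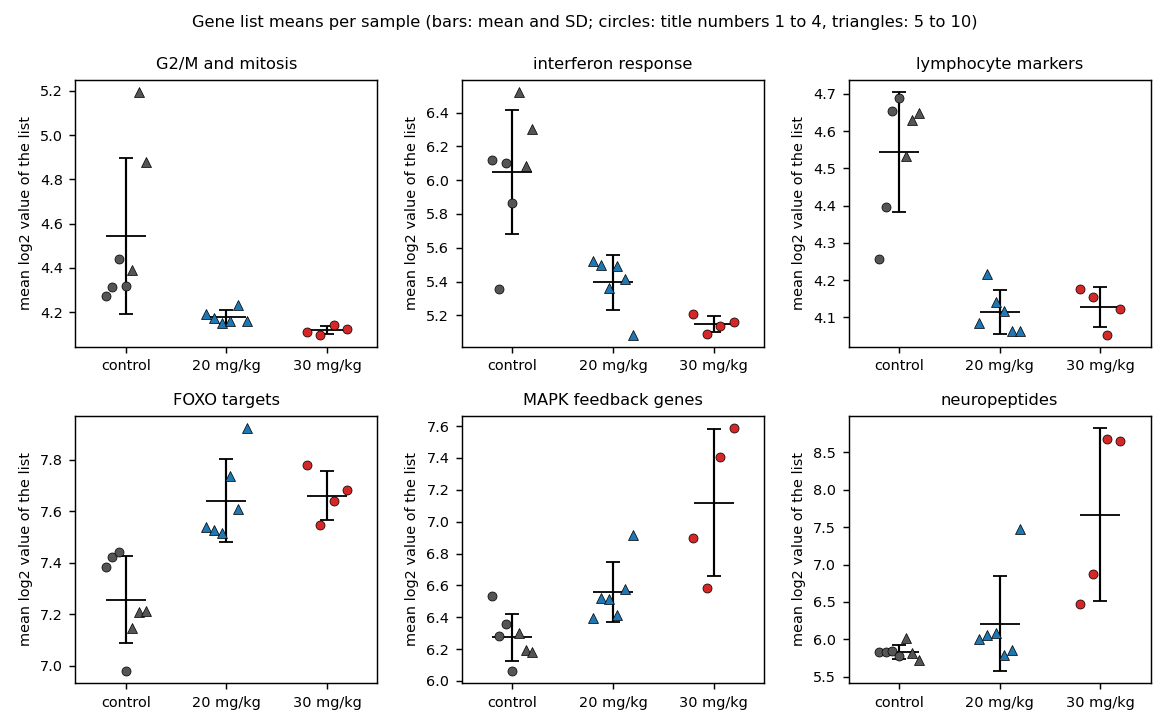
Mean log2 value of 6 gene lists (vertical axes) for each of 17 libraries by dose group; bars are the mean and SD, circles title numbers 1 to 4 and triangles numbers 5 to 10. In the G2/M and mitosis panel all 10 treated libraries lie below the lowest control, and in the neuropeptide panel replicates 3 and 4 at 30 mg/kg lie at 8.68 and 8.65.

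The other 17 lists did not pass. Their adjusted p was 0.23 for gonadotroph markers, 0.40 for chromaffin markers, 0.73 for ATF4 targets and amino acid supply, 0.80 for apoptosis regulators and 0.998 for pituitary receptors. It was 0.58 for Pou1f1-lineage, corticotroph and melanotroph, folliculostellate and stem cell, and neutrophil markers, p53 targets and the neuroendocrine secretory machinery. It was 0.77 for posterior pituitary and glial markers and for glycolysis and hypoxia, and 0.86 for PI3K, AKT and mTOR pathway components, NRF2 and AhR targets, and D cyclins and cell cycle inhibitors. Single members passed over all genes in 5 of the lists that did not pass. These were the transcription factor Gata2 (-0.77 ± 0.19, adjusted p = 0.048), Pik3r1, the regulatory subunit of PI3K (-0.64 ± 0.14, adjusted p = 0.030), the somatostatin receptor Sstr2 (-0.68 ± 0.15, adjusted p = 0.033), cyclin gene Ccnd1 and Rrm2. Among ATF4 targets, Pycr1 (-0.74 ± 0.14) and Phgdh (-0.39 ± 0.09) fell while Atf4 itself rose by 0.66 ± 0.16 (adjusted p = 0.019, 0.042 and 0.045). Median, mean and test had the same sign in all 16 called lists; they differed for D cyclins and cell cycle inhibitors (median -0.11, mean 0.06) and for pituitary receptors, whose median (0.07) and mean (0.10) were positive and test negative.

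At 30 mg/kg, genes of neuropeptides and secreted regulators rose furthest. Adcyap1, the gene of PACAP, rose by 3.97 ± 0.92 on the log2 scale (SE; limma adjusted p = 0.013), neurotensin Nts by 3.85 ± 0.94 (adjusted p = 0.018), neuromedin Nmu by 3.77 ± 0.62 (adjusted p = 0.0019), urocortin Ucn2 by 3.76 ± 0.82 (adjusted p = 0.0099) and Vgf by 3.70 ± 0.56 (adjusted p = 0.0010). Ccl11 (-4.76 ± 0.65), Hbb (-3.51 ± 0.50), Fabp6 (-3.40 ± 0.55), the angiotensin receptor gene Agtr2 (-3.39 ± 0.59) and Hbb-b1 (-3.38 ± 0.55) fell furthest. Against the 7 controls, 1240 genes passed, 531 higher and 709 lower. The count was 251 in female rats, 532 in a fit of only these groups, 437 with the title-number set as a term and 16 within numbers 1 to 4. Within numbers 1 to 4 only Hbb of the 10 genes kept its call (-4.15 ± 0.43, adjusted p = 0.017). Adcyap1 was 3.07 ± 1.27 there, Nts 3.36 ± 1.34, Nmu 3.51 ± 0.99, Ucn2 2.82 ± 0.84 and Vgf 3.22 ± 0.66 (adjusted p = 0.50, 0.47, 0.30, 0.32 and 0.16), and Ccl11 was -4.14 ± 0.74, Fabp6 -2.80 ± 0.53, Agtr2 -2.67 ± 0.75 and Hbb-b1 -4.15 ± 0.64 (adjusted p = 0.11, 0.12, 0.30 and 0.072). These calls ended in a fit of fewer libraries with a smaller change for all but Hbb-b1 and a larger SE for all but Fabp6. It was 799 without replicate 3 at 30 mg/kg, 456 without replicate 4 and 155 without both, which had the highest scores on the first principal component (44.4 and 47.1). The calls of Adcyap1, Nts and Ucn2 were lost without replicate 4 at 30 mg/kg, and that of Nts also without replicate 3. Chromaffin markers in the same libraries did not pass as a list (mean log2 change -0.60, adjusted p = 0.065; adjusted p = 0.46 with an estimated correlation). Of the 8 genes, 2 were lower over all genes, Ddc and Hand2, named after their values were seen, and 3 were lower and 1 higher adjusted over the list alone. The median of these markers was 8.04 and 8.43 in replicates 3 and 4 at 30 mg/kg, against 9.96 to 10.51 in controls, while Th was 12.52 at 30 mg/kg and 12.10 in controls (adjusted p = 0.075).

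At 30 mg/kg, 14 lists passed with the preset correlation and 0 with an estimated one. Immediate early genes (mean 1.12; adjusted p = 0.27 with an estimated correlation), MAPK feedback genes (0.85; adjusted p = 0.092) and endothelial markers (0.55; adjusted p = 0.15) rose, with 7 of 15, 5 of 11 and 4 of 12 genes higher over all genes. Adjusted over the list alone, 10, 10 and 9 were higher, and 1 endothelial gene was lower. Interferon response genes fell (mean -0.90; adjusted p = 0.13 with an estimated correlation), with 7 of 14 lower over all genes and 9 adjusted over the list alone. Macrophage markers also fell (-0.56; adjusted p = 0.29), with 5 of 12 lower and 7 adjusted over the list alone.

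At 20 mg/kg, Sv2c (1.44 ± 0.33), Use1, an endoplasmic reticulum SNARE (1.42 ± 0.23), Depp1 (1.27 ± 0.17), the stress gene Ddit3 (1.2 ± 0.26) and Ngdn (1.11 ± 0.25) rose furthest (SE; limma adjusted p = 0.042, 0.010, 0.0022, 0.037 and 0.037). Fabp6 (-2.61 ± 0.49), Oasl (-2.54 ± 0.25), Cxcl10 (-2.16 ± 0.42), Fads1 (-1.82 ± 0.35) and F11r (-1.82 ± 0.33) fell furthest, with adjusted p of 0.022, 9.6e-05, 0.022, 0.022 and 0.021. In all 171 genes passed, 95 higher and 76 lower, and 10 lists did, 1 of them, lymphocyte markers, with an estimated correlation (adjusted p = 0.018). The endothelial, macrophage and immediate early lists, called for both doses together, did not pass at 20 mg/kg against all controls (camera adjusted p = 0.57, 0.54 and 0.57). Nor did the oxidative phosphorylation, lysosome and autophagy, and MAPK feedback lists (0.94, 0.17 and 0.12). Within numbers 5 to 10 camera called the endothelial, macrophage and immediate early lists (adjusted p = 0.0068, 0.0068 and 0.037). It also called the oxidative phosphorylation, lysosome and autophagy, and MAPK feedback lists there (2.9e-05, 0.0068 and 0.00061). In the same order, exact permutation of list means there gave p = 0.012, 0.14, 0.36, 0.060, 0.15 and 0.036. The balance of higher and lower genes depended on scaling: quantile normalization gave 38 higher and 65 lower, and median centring 195 higher and 73 lower. The count was 55 without the sex term, 577 with array weights, 2 in female rats, 273 over all probe sets, 52 (3 higher and 49 lower) with the title-number set as a term, and 173 (31 higher and 142 lower) within numbers 5 to 10. It was 98, 470 and 81 without control replicates 1, 5 and 7, and 32, 22, 26 and 65 without replicates 6, 7, 8 and 10 at 20 mg/kg. Within numbers 5 to 10, Use1 shrank to 0.85 ± 0.13 but kept its call (adjusted p = 0.014), as did Depp1, Fabp6, Oasl and Cxcl10. Ddit3 (0.60 ± 0.22) and Ngdn (0.43 ± 0.16) lost theirs as the change shrank (adjusted p = 0.20 and 0.21), and Sv2c (1.60 ± 0.38), Fads1 (-2.02 ± 0.45) and F11r (-2.06 ± 0.45) as the SE grew in a fit of fewer libraries (adjusted p = 0.075, 0.060 and 0.059). Without replicate 8 at 20 mg/kg only Oasl, Use1 and Depp1 of the 10 genes kept their calls, and the calls of Fads1, Sv2c, Ddit3 and Ngdn were also lost without replicates 6, 7 or 10, that of Cxcl10 without replicates 6 or 7, and those of Sv2c, Ddit3 and Ngdn without control replicates 1, 4 or 6.

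Both doses were set against the same controls. They shared 19 genes called higher and 48 called lower, with 0 in opposite directions; independent lists of these sizes would share 3.48 and 3.72, figures that make no allowance for the shared controls. Across genes, which are not independent replicates, the changes correlated at r = 0.294, against 0.409 in the simulations without effect, and their covariance was 0.0337 against 0.0126. With controls split so that each dose met those of its own title numbers, 2 higher and 6 lower calls were shared (r = 0.47). With the controls swapped, 3 higher and 12 lower calls were shared, 149 were opposite, and r was -0.293. The covariance was 0.0494 with controls of the same numbers and -0.0611 with the controls swapped. It changed sign with the choice of controls, so its comparison with the simulations cannot show that the doses share an effect.

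The doses themselves differed at many genes. Adcyap1 (3.30 ± 0.95), Ucn2 (2.77 ± 0.85), Agrp, the agouti-related peptide (2.73 ± 0.57), Vgf (2.71 ± 0.58) and Lynx1 (2.46 ± 0.52) were higher at 30 than at 20 mg/kg, with limma adjusted p of 0.033, 0.042, 0.0093, 0.010 and 0.0095. Tspan8 (-3.12 ± 0.65), Ccl11 (-2.67 ± 0.67), Lix1 (-2.51 ± 0.59), Tm4sf4 (-2.38 ± 0.48) and Eaf2 (-2.31 ± 0.44) were lower, with adjusted p of 0.0093, 0.019, 0.014, 0.0079 and 0.0060. Between the doses 1752 genes passed, 569 higher and 1183 lower at 30 mg/kg (606 and 765 with quantile normalization, 366 and 1440 with median centring). The doses have different title numbers, so dose and set can be compared only through the controls of each set. With the set as a term limma called 0 genes (971 at an unadjusted p under 0.05), and with the SD of each array as a covariate 0 (1389 unadjusted). Array SD lay between 2.145 and 2.204 at 20 mg/kg and between 2.063 and 2.109 at 30 mg/kg, so it separates the doses as the set does. Among the controls it separates the sets too (2.043 to 2.109 for numbers 1 to 4, 2.139 to 2.205 for numbers 5 to 7). The calls ended both because changes shrank and because their SE grew: over the 1752 genes the median size of the change was 0.763 with a median SE of 0.192 before, 0.355 and 0.281 with the set, and 0.486 and 0.274 with array SD. For Agrp the change was 2.73 ± 0.57 before, 2.42 ± 0.96 with the set and 2.74 ± 0.90 with array SD. The count was 405 in female rats, 2649 in a fit of only the treated groups, 1164 without replicate 3 at 30 mg/kg, 321 without replicate 4 and 51 without both, and 923, 1125 and 874 without replicates 6, 7 and 8 at 20 mg/kg. Without replicate 4 at 30 mg/kg only Agrp and Eaf2 of the 10 genes kept their calls, and the calls of Adcyap1 and Ucn2 were also lost without replicate 3 or any of replicates 5 to 9 at 20 mg/kg.

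Between the doses, 6 lists differed with the preset correlation and 0 with an estimated one. Immediate early genes were higher at 30 mg/kg (mean 0.99; adjusted p = 0.68 with an estimated correlation), with 5 of 15 genes higher over all genes and 7 adjusted over the list alone. MAPK feedback genes (mean 0.58; adjusted p = 0.68), endothelial markers (0.48; adjusted p = 0.68) and neutrophil markers (0.58; adjusted p = 0.68) were also higher. Of these, 3 of 11, 3 of 12 and 1 of 6 genes passed over all genes, and 5, 7 and 2 adjusted over the list alone. Oxidative phosphorylation genes (mean -0.29; adjusted p = 0.79 with an estimated correlation) and macrophage markers (-0.41; adjusted p = 0.71) were lower, with 3 of 23 and 5 of 12 genes over all genes and 7 and 5 adjusted over the list alone. With the set as a term 5 lists passed, 0 of them among these 6, and with array SD as a covariate 5 passed, 2 of them among the 6, endothelial markers and MAPK feedback genes. Without replicate 4 at 30 mg/kg the calls of macrophage, neutrophil and oxidative phosphorylation genes were lost (adjusted p = 0.096 for each), and without replicate 3 that of neutrophil markers (0.25). The macrophage call was also lost without replicates 1 or 2 at 30 mg/kg (0.088 and 0.12), control replicate 1 or replicate 7 at 20 mg/kg, and the neutrophil call without control replicates 1, 2, 3 or 7 or replicates 5, 7, 8 or 10 at 20 mg/kg.

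**Figure D4:**
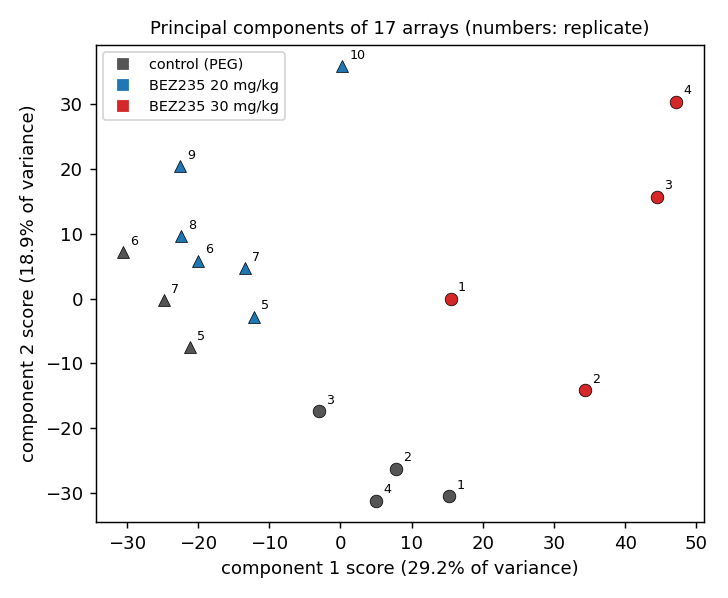
Scores of the 17 arrays on the first and second principal components (29.2% and 18.9% of variance); colours are dose groups, numbers are title numbers, circles are numbers 1 to 4 and triangles numbers 5 to 10. Control arrays 5 to 7 lie beside the 20 mg/kg arrays, and replicates 3 and 4 at 30 mg/kg have the highest scores on the first component, 44.4 and 47.1.

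Male rats had higher levels of Cox4i2, a hypoxia-related cytochrome oxidase subunit (3.22 ± 0.63, SE), the adenosine receptor gene Adora2a (2.73 ± 0.39), Pkib (2.21 ± 0.40), Gpr139 (2.2 ± 0.42) and Spock1 (2.09 ± 0.40), with limma adjusted p of 0.039, 0.022, 0.028, 0.033 and 0.033. Vnn1 (-1.53 ± 0.26, adjusted p = 0.025) and Lmcd1 (-0.54 ± 0.10, adjusted p = 0.032) were lower in male rats. In all 35 genes passed between 5 male and 12 female libraries, 33 higher and 2 lower in males (29 and 8 with quantile normalization). That balance did not hold with the title-number set as a term (68 higher and 60 lower) or with array SD as a covariate (2 higher and 9 lower). Sex overlaps the set, since of the 5 males only replicate 4 at 30 mg/kg is in numbers 1 to 4. The count was 639 with array weights, 128 with the title-number set as a term and 215 without replicates 3 and 4 at 30 mg/kg, and, leaving out 1 library, 0 without control replicate 6 (1390 at an unadjusted p under 0.05), without replicate 1 at 30 mg/kg (2117) or without replicates 5 (2150) or 9 (1917) at 20 mg/kg. It was 23 and 13 without control replicates 2 and 7, 82 and 181 without replicates 3 and 4 at 30 mg/kg, and 9, 21, 59 and 1 without replicates 6, 7, 8 and 10 at 20 mg/kg. None of the 7 named genes passed without replicate 10 at 20 mg/kg.

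The effect of treatment differed between the sexes for 1 gene, Top2a (log2 difference of the effects -2.04 ± 0.29, SE; limma adjusted p = 0.037). Its log2 value was 6.59 ± 0.58 (SD) in the 2 male controls, 4.6 ± 0.34 in 5 female controls, 3.76 ± 0.10 in 3 treated males and 3.81 ± 0.17 in 7 treated females. The Top2a call was lost with the title-number set as a term. Its treated means lie within the range of the arrays' lower quartiles (3.65 to 3.91), below which differences are compressed. No interaction passed in the positive direction; Prss22 (0.89 ± 0.18), Cldn3 (0.98 ± 0.21) and Zic4 (0.73 ± 0.17) had the smallest p there, with adjusted p of 0.35, 0.35 and 0.47. Without control replicate 7, 14 genes passed, without control replicate 5, 2 and without replicate 9 at 20 mg/kg, 4, while leaving out any other library but control replicate 3 or replicate 2 at 30 mg/kg gave 0 (527 to 1190 genes at an unadjusted p under 0.05). Only 2 control libraries were male, so leaving out control replicate 6 or 7 leaves 1, which is assumed to vary like the other groups.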

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

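The tests of tissue identity, of array SD and of dose with the title-number set as a term, and all tests of the interferon list below, were chosen after the results were seen; the ratio of control to dose differences and the counts over other splits of the samples were set before.

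The catecholamine enzymes Th and Dbh and the steroidogenic gene Star lay above the upper quartile of every array in libraries labelled pituitary adenoma. The pituitary hormone genes had means below the upper quartiles. The median of the 7 hormone genes lay below the array median in 17 of 17 arrays, which argues against pituitary tissue with a small admixture of adrenal tissue. In 17 of 17 arrays the medians of both adrenal lists lay above the upper quartile, and adrenal tissue under a pituitary label is a candidate explanation. The label contradiction was not resolved here, and no biological explanation was tested.

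Interferon response genes such as Mx2 and Cxcl10 fell with treatment. A difference between the sets of title numbers as the whole cause is argued against by the fall within both sets, the higher exact permutation p being 0.0286, the smallest for 4 against 4. If fewer macrophages lowered both lists alike, which was not tested, the interferon mean minus the macrophage mean would not change. The macrophage mean held 11 genes, and sex was not accounted for. Cd74 (log2 change -1.49 with treatment) was left out of it, which makes the macrophage fall smaller. The interferon mean minus the macrophage mean changed by -0.542 over all samples (exact permutation p = 0.0014, title number not accounted for). Within numbers 5 to 10 it changed by -0.724 (exact permutation p = 0.0119, the smallest possible). On that assumption this argues against macrophage loss as the whole cause there. Within numbers 1 to 4 the change was -0.384 (exact permutation p = 0.2), and macrophage loss stays open. Fewer lymphocytes stay open, since 8 of 9 lymphocyte genes had means below the array median. An effect of the inhibitor on interferon signalling may remain but was not tested apart from cell content.

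Neuropeptide genes such as Adcyap1 and Ucn2 were higher and Ccl11 lower at 30 than at 20 mg/kg, with 1752 genes and 6 lists called. Dose and title-number set cannot be told apart: over the called genes the control difference between the sets was 0.489 of the dose difference, just under the level set in advance for a cause, with the same sign for 1550 of 1752 genes, and of 35 splits of the controls 1, the real one, was as large (highest other 0.289). This control difference took no account of sex, and both male controls are numbered 6 and 7, so the ratio and its rank mix set with sex. With the set as a term limma called 0 genes for dose (971 at an unadjusted p under 0.05) and 5 lists, 0 of the 6 among them. The same fit called 523 genes for the set itself. With array SD as a covariate 0 genes (1389) and 5 lists were called, 2 of the 6 among them. Array SD separates the doses completely (2.145 to 2.204 at 20 mg/kg, 2.063 to 2.109 at 30 mg/kg). It also separates control arrays 1 to 4 (2.043 to 2.109) from control arrays 5 to 7 (2.139 to 2.205), so it follows the set without the inhibitor. Over the 1752 genes the median change of 0.763 (median SE 0.192) became 0.355 (0.281) with the set and 0.486 (0.274) with array SD. Neither fit can therefore decide. Tissue markers shifted as well, with chromaffin genes lower (mean -0.58, 3 of 8 genes past the threshold, list adjusted p = 0.24) and adrenal cortex genes higher (mean 0.52, camera p = 0.00041; 0.16 with an estimated correlation), and without replicates 3 and 4 at 30 mg/kg, whose chromaffin medians were 8.04 and 8.43, 51 genes passed. Dose, an unrecorded difference between the sets or a different tissue content, which was not tested, could give these genes.

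Other splits of the samples into groups of the same sizes, 100 per comparison, were counted. For treatment against control 2 of the 100 splits, the real one included, called at least 215 genes, a share under 0.05. The other called 806, several times the real count, which points to some structure of the samples. Which samples it grouped was not examined. For its 16 lists 1 split, the real one, was as large (highest other 15), also a share under 0.05. The same held for 30 mg/kg (1240, highest other 936), 20 mg/kg (171, highest other 4) and between the doses (1752, highest other 1186). For the 6 lists between the doses 16 splits were as large (highest other 10), so chance is not excluded. Between the sexes 2 splits gave at least 35 genes, a share under 0.05, but the other gave 487, and which samples it grouped was not examined either. The splits took no account of title number. A share under 0.05 therefore makes a random regrouping an unlikely source of a count, but does not exclude a difference between the sets.

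The effect of treatment on Top2a differed between the sexes by -2.044 on the log2 scale, the 1 gene with an interaction past the threshold. Among 13904 probe sets not used as genes, 63 passed for treatment against control, 36 higher and 27 lower.

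Single samples far from the rest of their group were sought by the gap to the nearest sample divided by the range of the group. Of 480 groups tested, over 127 genes and 33 list means, 41 had such a sample, and chance gives about 1 in 20 of groups. The genes were limited to named genes of called comparisons and lists and the chromaffin genes after the result for all named genes had been seen. Replicate 10 at 20 mg/kg accounted for 18. It was highest for Ifrd1 (gap 0.783), Luc7l (0.665), Flt1 (0.651), Pdk4 (0.637), Atf4 (0.686), Nop56 (0.7), Dusp1 (0.898), Nr4a2 (0.834), Spry2 (0.756), Adcyap1 (0.739), Nts (0.653), Ucn2 (0.712) and Agrp (0.754), and for the means of immediate early (0.718) and MAPK feedback genes (0.658). It was lowest for Aif1 (0.627), Eaf2 (0.652) and the interferon response mean (0.639). Also at 20 mg/kg, replicate 9 was highest for Pomc (0.691) and Oas1a (0.743), and replicate 6 lowest for Tshb (0.822). At 30 mg/kg, replicate 4 was highest for Luc7l (0.863), Hbb (0.842), Cga (0.845) and Zic4 (1), replicate 2 for F11r (0.845) and Phgdh (0.944), and replicate 1 for Bcl2l11 (0.92) and Eaf2 (0.841), while replicate 1 was lowest for Lynx1 (0.959). Among controls, replicate 3 was highest for Cga (0.662), Hba-a3 (0.614) and the erythroid mean (0.624), replicate 2 for Prl (0.63) and Col1a2 (0.586), replicate 6 for Agrp (0.789) and replicate 4 for the pituitary receptor mean (0.676). Control replicate 5 was lowest for Th (0.602), replicate 1 for Ddc (0.59) and Agtr2 (0.597), and replicate 2 for the macrophage mean (0.594).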

How the results depend on the processing

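Title-number set as a term, each set alone, the SD of each array as a covariate, and the fit without replicates 3 and 4 at 30 mg/kg were chosen after the data were seen. Counts are of limma calls, and the cause was not tested where a count changed, except that a stricter threshold lowers counts by construction. Over the settings other than leaving out 1 library, 72 values of the counts and of the G2/M mean stayed within 1.5 times the reported count, or past the threshold, and 62 did not. For lists 179 calls held, 69 were lost and 4 changed sign; for named genes 1633 stayed on their side of the threshold, 280 calls were lost, 73 were gained and 0 changed sign. The difference in G2/M mean (-0.39) ranged from -0.65 within numbers 5 to 10 to -0.20 in female rats on the log2 scale, and was -0.86 as z-scores.

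For treatment against control (215 genes), the count was 100 (25 higher, 75 lower) without the sex term, 424 with array weights, 138 among probe sets above the median, 28 at adjusted p under 0.01, 59 at 2-fold or more, 12 in female rats, 569 as the average of both dose effects, 449 with dose as a number, 712 with the set as a term, 16 within numbers 1 to 4 and 507 with array SD. Median centring gave 83 higher and 101 lower. Of 16 lists, 3 were called with an estimated correlation and 10 by fry, and oxidative phosphorylation turned to 0.0286 in female rats.

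For 30 mg/kg against control (1240) it was 383 at adjusted p under 0.01, 429 at 2-fold or more, 251 in female rats, 532 with only these groups, 437 with the set, 684 with array SD and 155 without replicates 3 and 4. For 20 mg/kg (171) it was 55 without sex, 577 with array weights, 103 with quantile normalization (38 higher, 65 lower), 268 with median centring (195 higher, 73 lower), 273 over all probe sets, 12 at adjusted p under 0.01, 41 at 2-fold or more, 2 in female rats, 52 with the set and 29 with array SD.

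Between the doses (1752) the count was 302 at adjusted p under 0.01, 490 at 2-fold or more, 405 in female rats, 2649 with only these groups, 0 with the set (971 at an unadjusted p under 0.05), 0 with array SD (1389) and 51 without replicates 3 and 4. Quantile normalization gave 606 higher and 765 lower, and median centring 366 and 1440. Over the called genes the median size of the change was 0.763 (median SE 0.192), and 0.355 (0.281) with the set and 0.486 (0.274) with array SD. Of 6 lists, 0 stayed called with the set and 2 with array SD, with 5 called in each fit; 0 were called with an estimated correlation, 3 by fry and 3 without replicates 3 and 4. Oxidative phosphorylation turned to 0.117 with the set, macrophage markers to 0.0287 with array SD and neutrophil markers to -0.0454 without replicates 3 and 4.

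Between the sexes (35) the count was 639 with array weights, 94 with median centring, 21 above the median, 0 at adjusted p under 0.01 (2221 unadjusted), 19 at 2-fold or more, 128 with the set (68 higher, 60 lower), 11 with array SD (2 higher, 9 lower) and 215 without replicates 3 and 4. For the interaction (1) it was 29 with array weights and 0 with quantile normalization (782 unadjusted), over all probe sets (1951), above the median (350), at adjusted p under 0.01 (951), with the set (663), with array SD (538) and without replicates 3 and 4 (718).

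No pairing of samples by title number was seen: over 7 pairs of equal number, residuals of treated and control arrays correlated between -0.183 and 0.0849, 0 pairs lay above 0.1, and 1 number matched its own partner best. Control residuals were taken around the mean of all controls, so they carry the difference between the sets, which treated residuals do not. A weak pairing could therefore be missed. With the number as a replicate block, limma called 231 genes for treatment against control, 72 for 30 mg/kg, 0 for 20 mg/kg (805 unadjusted), 0 between the doses (588; 0 lists), 0 between the sexes (1831) and 0 for the interaction (981).

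Leaving out 1 library at a time gave 46 (without control replicate 7) to 249 genes and 14 to 17 lists for treatment, 456 to 1563 genes for 30 mg/kg, 22 to 470 for 20 mg/kg, 321 to 2172 between the doses with 4 to 7 lists, 0 (1390 to 2150 unadjusted) to 181 between the sexes, and 0 (527 to 1190 unadjusted) to 14 for the interaction. The G2/M difference stayed between -0.44 and -0.28. In these fits 104 values held and 49 moved by more than 1.5 times; 345 list calls held and 29 were lost; and among named genes 2869 held, 346 calls were lost and 15 gained. Signal near background limits the G2/M and lymphocyte lists, whose means lie below the array median in the treated libraries.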

Other observations

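The lists and genes in this part were chosen after their values were seen, and their p-values are unadjusted camera p-values unless stated.

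Class II antigen presentation genes, which display peptides to T cells, were lower in treated libraries. The median log2 change of the 8 genes was -1.25 (p = 9.1e-11; p = 0.0064 with an estimated correlation), and 4 of the 8 passed over all genes. Against control it was -1.71 at 30 mg/kg (p = 0.0060 with an estimated correlation; 7 of 8 genes lower) and -0.81 at 20 mg/kg (p = 0.020; 3 lower). RT1-Da, a class II chain, fell by 2.90 at 30 mg/kg (limma adjusted p = 0.00012) and RT1-Ba by 2.19 (adjusted p = 0.00015). Cd74, which is also a member of the macrophage list, fell by 2.19 (adjusted p = 0.0006). The macrophage and lymphocyte lists fell as well (mean -0.31 and -0.43 for treatment; macrophage -0.56 at 30 mg/kg with 5 of 12 genes lower), so a change in cell content is not separated from a change in expression. The 9 immunoproteasome and class I genes had a median of -0.24 for treatment (p = 0.035 with an estimated correlation; 0 genes passed in limma at the adjusted threshold) and -0.57 at 30 mg/kg (p = 0.0075; 4 lower).

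Neuropeptide genes were higher at 30 mg/kg, with a median of 1.79 over 18 genes (p = 1.3e-09; p = 0.016 with an estimated correlation), and 11 genes higher. Calca, the gene of calcitonin and CGRP, rose by 2.66 (limma adjusted p = 0.0054), Tac1 by 2.77 (adjusted p = 0.040), Penk by 2.11 (adjusted p = 0.026) and Npy by 1.48 (adjusted p = 0.0015). At 20 mg/kg the median was 0.36 (p = 0.65 with an estimated correlation). The list mean was 5.83 ± 0.09 (SD, n = 7) in controls, 6.21 ± 0.63 (n = 6) at 20 mg/kg and 7.67 ± 1.16 (n = 4) at 30 mg/kg, with replicates 3 and 4 at 30 mg/kg at 8.68 and 8.65 and replicate 10 at 20 mg/kg at 7.48.

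Single chromaffin and adrenal cortex genes also differed, while the chromaffin list at 30 mg/kg did not pass (mean -0.60, adjusted p = 0.065; 0.46 with an estimated correlation; 2 of 8 genes lower). Ddc, the aromatic amino acid decarboxylase, fell by 1.95 at 30 mg/kg against control (limma adjusted p = 0.0013), and the transcription factor Hand2 by 1.71 (adjusted p = 0.00075), whereas Th was 0.43 higher without passing (adjusted p = 0.075). Replicates 3 and 4 had the lowest chromaffin medians, 8.04 and 8.43. Mrap, a cofactor of the ACTH receptor, rose by 1.38 at 30 mg/kg (adjusted p = 0.0019), while the ACTH receptor gene Mc2r fell by 1.47 at 20 mg/kg (adjusted p = 0.017). The 11 adrenal cortex genes had a median of 0.47 between 30 and 20 mg/kg (p = 0.16 with an estimated correlation, 4 higher). Against control their median was -0.36 at 20 mg/kg (p = 0.0019, and 0.22 with an estimated correlation, 2 lower). At 30 mg/kg it was 0.11 (p = 0.17, and 0.58 with an estimated correlation, 1 higher).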
